A study of Mus musculus with 12 samples.

How the data were processed

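RNA of the hippocampus of adult female C57BL/6J mice, 12 weeks old by label, was measured on Illumina bead arrays with 1 colour, 1 array per sample. The labels put 6 arrays in the ethanol-exposed group (EtOH) and 6 in the Control group. Per the labels, exposed dams drank 10% v/v ethanol by choice between 0.5 and 8.5 days post-coitum. The same treatment text stands on every sample, Control included, so the groups were taken from the sample titles. The labels do not tell litters apart. The p-values therefore treat each array as independent, although siblings may share a dam, and measure the spread between arrays only.

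The deposited table holds, per the file headers, the signal intensity of 45281 probes on each array, on a linear scale and not normalized. Beside each intensity the authors deposited a detection p-value, which sets the probe against the array's negative controls. GenomeStudio version 1.9.0 is named in the submitters' processing notes. A second deposited table of intensity values per array was compared with the first. Its columns ranked the probes like the matching array (lowest Spearman correlation 1.00, highest with any other array 0.932) and had nearly equal medians, from 135.6 to 135.7, and shared quantiles within 1.75% of the mean of the sorted first table, so it holds quantile-normalized intensities on a linear scale. It served as an alternative. No column lacked a known sample.

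Intensities were background-corrected and quantile-normalized on the log2 scale with neqc of limma 3.58.1 in R 4.3.3 (offset 16, background from the detection p-values). A probe was kept where its detection p-value was under 0.05 on at least 6 of the 12 arrays, whatever their group, which left 20172 probes. Gene names came from the platform annotation, where 34885 probes name 1 gene, 18 name several and 10378 name none. The check against current mouse symbols of the GRCm38.p6 annotation changed 0 of them. The kept probes named 10936 genes through 17117 probes. The genome build of the probes is not given, and no positions are used. No gene was named from a probe with several.

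The sample titles divide the arrays over 2 chips of 6. Chip 1 held 4 EtOH and 2 Control arrays and chip 2 held 2 EtOH and 4 Control arrays. The groups were compared with two-sided tests of limma (lmFit and eBayes, default settings) with the chip as a fixed term, and p-values were adjusted by the Benjamini-Hochberg method over the kept probes, with a threshold of 0.05. Differences are EtOH minus Control on the log2 scale, adjusted for the chip. The group means beside them are not adjusted, so the 2 can differ. Intervals are 95% confidence intervals from the same fit. No array duplicated another: the correlation between arrays ran from 0.983 to 0.994.

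Before the data were examined, 34 gene lists were fixed from textbook knowledge. They covered hippocampal neurons, glia, vessels, tissues that a dissection can carry over, transmitter receptors, activity-dependent genes, DNA methylation, histone enzymes, imprinting, ethanol and one-carbon metabolism, stress and housekeeping. Each was tested with camera of limma (preset inter-gene correlation 0.01) on 1 probe per gene, the brightest, with Benjamini-Hochberg adjustment over the lists. Several lists share genes. Slc17a6, with Slc17a7 and Slc17a8, was set as a candidate beforehand and also tested with a two-sided exact permutation of the group labels within chips. Genes are named in the text by a fixed rule. It takes up to 10 genes per direction past the threshold by size, with open places filled by the smallest unadjusted p, each gene once and unnamed probes passed over. It adds 3 members with the smallest p of each list past its test and 1 of every other list, the 3 candidates, and Xist, Ddx3y and Eif2s3y as a check of sex. Genes named outside this rule were chosen after their values were seen, and the text says so.

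The fit was tested on simulated data with 200 of 20172 probes changed and independent noise. In the comparison of EtOH with Control it recovered 0.15% of changes of 0.25 on the log2 scale, 67.8% of changes of 0.50 and 98.6% of changes of 1, with 6.7 and 10.1 false calls on average for the 2 larger sizes. A list shifted by 0.15 was called in 9 of 10 simulations. With no change it called 0 probes. Real arrays share variation that independent noise leaves out, which the regroupings in the closing section address. The number of arrays limits the precision. The median half-width of the 95% interval of a difference was 0.20 on the log2 scale, and for most probes it lay between 0.13 and 0.39 (the 5th and 95th percentiles).

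Alternatives fixed beforehand changed the background correction, the normalization, the filter, the chip term (left out, as a random block, each chip alone), the variance model, array weights, a block for the replicate number, and left out each array in turn. For the lists, an estimated correlation, the fry test and the mean of a gene's probes were also tried. Alternatives chosen after seeing the data were the removal of 4 arrays with choroid plexus transcripts and the choroid plexus and neocortex list means as covariates. An exact permutation of list means, and the meninges list without Slc13a4, Igf2 and Igfbp2, were also chosen then.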

Results

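Hippocampal transcripts of adult female mice were profiled on 12 bead arrays, 6 from offspring of dams that drank ethanol in early pregnancy and 6 from Control offspring. The labels name the question as gene expression in the brain after exposure to ethanol in early pregnancy. Median raw intensity ran from 126 to 146.9 per array, and between 19748 and 20858 probes per array were detected. Both bright probes of Xist, the RNA that silences an X chromosome in females, lay between 10.57 and 11.33 on the log2 scale on the 12 arrays. The Y-linked gene Eif2s3y was detected on at most 2 of 12 arrays by either of its probes, near background. Ddx3y, without a probe of its own name, was not analysed here.

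Transcripts of the choroid plexus, the secretory tissue of the brain ventricles, divided the arrays into sets of 4 and 8. Ttr (transthyretin), its most abundant product, reached 15.39 to 15.47 in EtOH 2, EtOH 4, Control 2 and Control 4 and stayed between 7.92 and 11.57 in the other 8 arrays. Clic6 had a median of 11.56 in the 4 arrays against 5.31 in the other 8, and the anti-ageing gene Kl had 10.33 against 7.49. Igf2, a growth factor that the plexus and meninges share, had medians of 13.18 and 11.30. The ependymal gene Rsph1 went with them, at 9.49 and 8.34. Not every gene of the ependyma list did: Dnah11 ran from 6.18 to 6.245 on the 4 arrays and from 6.052 to 6.348 on the other 8. Ttr, Kl, Clic6, Igf2, Rsph1 and Dnah11 were chosen for mention here after their values were seen. Neuronal genes did not divide this way: Wfs1 of CA1 pyramidal cells had medians of 10.11 and 10.21, and Slc17a7 had 11.94 and 11.88. Each group held 2 of these 4 arrays, but EtOH 2, EtOH 4 and Control 2 were on chip 1 and Control 4 was on chip 2. The groups were therefore not balanced for these arrays once the chip was adjusted for.

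**Figure D1:**
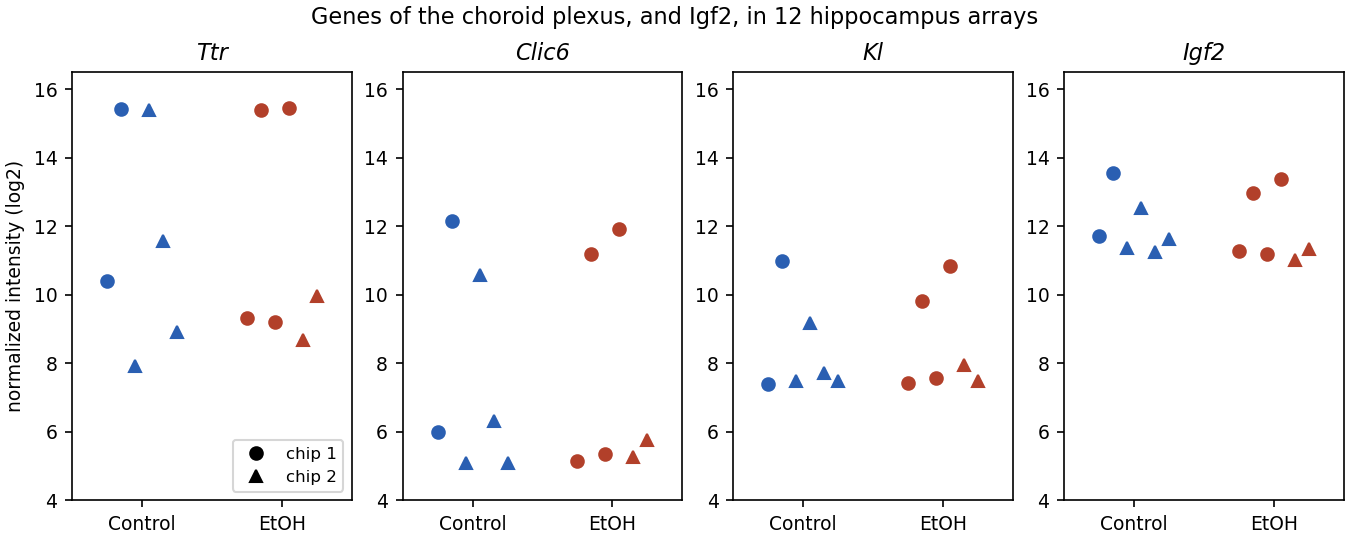
Normalized log2 intensity of Ttr, Clic6, Kl and Igf2 on each of the 12 arrays, by group (horizontal axis) and chip (symbol). In each panel 2 Control and 2 EtOH arrays lie above the rest of their group, with Ttr between 15.39 and 15.47 on those 4 arrays.

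Between EtOH and Control hippocampus, no single transcript passed the threshold. The lowest p among named genes belonged to Slc6a12, the betaine and GABA transporter BGT1, at 5.73 ± 0.25 in EtOH and 6.32 ± 0.29 in Control (log2 mean ± SD, n = 6 each). Its difference was -0.70 (95% interval -0.97 to -0.43), and 6 of 6 EtOH arrays lay below the Control median. Among genes with higher values, Tpmt, which methylates thiopurines, stood at 6.13 ± 0.05 in EtOH and 5.82 ± 0.11 in Control, a difference of 0.33 (0.20 to 0.47), with 6 of 6 EtOH arrays above the Control median. Neither passed: limma called 0 of 20172 probes higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 1.00. At an unadjusted p under 0.05 limma gave 702 probes, 354 higher and 348 lower, which is 3.48% where chance gives 5%.

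The other genes with the smallest p and higher values in EtOH had differences between 0.27 and 0.38. They were Orc2, a subunit of the origin recognition complex, at 0.27, and Zfp286 at 0.36. Dcaf10 differed by 0.35 and the heat shock protein gene Hspa4l by 0.32, although its other probe went the opposite way. Ttn (titin) differed by 0.38, and Mapk10, the neuronal JNK3 kinase, by 0.34, again with its other probe opposite. The anti-apoptotic Bcl2 differed by 0.37, the sphingosine phosphate receptor S1pr5 by 0.37 and Hook2 by 0.35. For Bcl2, 1 of 2 other probes went the opposite way. For S1pr5 only 2 of 6 EtOH arrays lay above the Control median before adjustment for the chip.

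Among genes with lower values, Ccl21c, a chemokine that draws lymphocytes, differed by -0.66. Its second probe (-0.58) and the probe of the near-identical gene Ccl21a (-0.59), chosen after its values were seen, had lower values too, so which copy was measured is uncertain. Rtn4rl2, of the Nogo receptor family, differed by -0.52 and Pttg1 (securin) by -0.52. H2-M10.1 differed by -0.48, the lysozyme gene Lyz1 by -0.45, Pigo by -0.41 and the growth factor receptor gene Fgfr2 by -0.37, the last with its other probe opposite. Ccnl1 differed by -0.28 and Tpd52l1 by -0.26. For Pigo and for Ccnl1, 1 of 2 other probes went the opposite way. Each of these genes has an adjusted p of 1.00 in limma. Several genes named for a small p, in either direction, lay close to background in 1 group. Mean levels in EtOH were 4.91 for H2-M10.1, 5.14 for Rtn4rl2 and 5.18 for Pttg1. In Control they were 5.37 for Orc2 and 5.38 for Ttn, and Slc6a12 was as low as 5.27 in EtOH 5. An Eif2s3y probe detected on only 2 of 12 arrays ran from 4.73 to 5.52. The chips themselves differed more than the groups, with 156 probes past the threshold for the chip term.

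Of 19 measured immediate early genes, which neurons switch on within minutes of stimulation, 16 had higher values in EtOH and 3 lower, with a median difference of 0.14 on the log2 scale. Camera at its preset correlation called this list (adjusted p = 0.000761), a call lost with an estimated correlation (adjusted p = 0.718 with an estimated correlation) and in fry (adjusted p = 0.905). The transcription factor gene Fos stood at 7.79 ± 0.42 in EtOH and 7.38 ± 0.28 in Control (n = 6 each), a difference of 0.50 (95% interval 0.10 to 0.90). Arc, which acts at synapses, differed by 0.34 (0.06 to 0.61) and the transcription factor gene Egr1 by 0.22 (0.03 to 0.42). No member passed the limma test over all genes (0 of 19), and 0 passed adjusted over the list alone, where the lowest adjusted p was 0.16. At an unadjusted p under 0.05 limma gave 5 members, 5 of them higher.

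For the immediate early list the exact permutation of the list mean within chips gave p = 0.04, and 0.879 after adjustment over 34 lists. The median was 0.21 within chip 1 and 0.11 within chip 2, and without the chip term it was 0.11 (camera adjusted p = 0.052). Neocortex genes, which share Nr4a2 with this list, had a median of 0.10. Of 100 divisions of the arrays into 6 and 6, the real one included, 81 gave at least 2 called lists.

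Of 13 measured genes of the meninges and vascular fibroblasts, 10 had lower values in EtOH and 3 higher, with a median difference of -0.43. Camera at its preset correlation called this list (adjusted p = 0.000761), a call lost with an estimated correlation (adjusted p = 0.85 with an estimated correlation) and in fry (adjusted p = 0.905). The organic anion transporter gene Slc22a6 stood at 6.31 ± 0.36 in EtOH and 6.77 ± 0.44 in Control (n = 6 each), a difference of -0.55 (95% interval -1.01 to -0.09). Mgp, an inhibitor of calcification, differed by -0.59 (-1.10 to -0.07) and the GABA transporter gene Slc6a13 by -0.45 (-0.89 to -0.02). The fibrillar collagen genes Col1a1 and Col1a2, chosen after their values were seen, had differences of 0.09 and 0.06 at levels between 5.32 and 5.41, close to background. In limma 0 of 13 members passed over all genes and 0 adjusted over the list alone (lowest adjusted p 0.186), with 3 lower members at an unadjusted p under 0.05.

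For the meningeal list the exact permutation of the list mean within chips gave p = 0.182. The median was -0.43 within chip 1 and -0.53 within chip 2. Without the chip term it was -0.24 (camera adjusted p = 0.128), and without Control 2 it was -0.18 (camera adjusted p = 0.307). Control 2 was 1 of the 4 arrays with choroid plexus transcripts and had the highest mean of the meninges list, 9.02. Choroid plexus genes, of which Slc13a4 belongs to both lists, had 9 of 9 members lower with a median of -0.59, a list that did not pass (camera adjusted p = 0.193). Without the chip term the choroid plexus median was smaller in size, at -0.10. The unadjusted group means of Kl, Calml4 and Trpv4, chosen after their values were seen, were higher in EtOH. The choroid plexus median turned to 0.12 without Control 2 and to 0.027 with the neocortex list mean as a covariate.

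**Figure D2:**
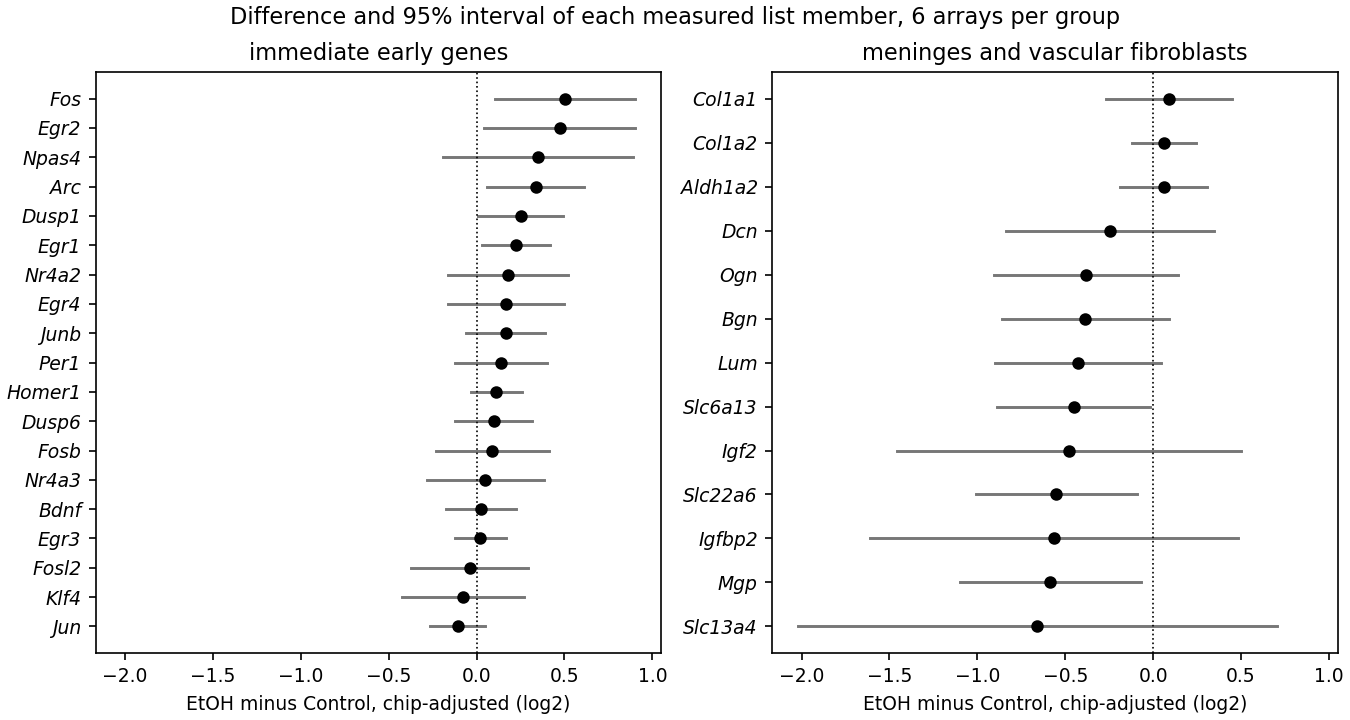
Chip-adjusted log2 difference, EtOH minus Control, of each measured member of the 2 called lists (points) with its 95% confidence interval (lines), from 6 arrays per group. The interval excludes 0 for 5 of 19 immediate early genes and for 3 of 13 meningeal genes, among them Fos at 0.50 and Slc22a6 at -0.55.

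Slc17a6, which encodes the vesicular glutamate transporter VGLUT2, was examined as a candidate because of an earlier report on adult hippocampus after this kind of exposure. It stood at 10.94 ± 0.72 in EtOH and 10.63 ± 0.66 in Control (log2 mean ± SD, n = 6 each). The difference of 0.35 (95% interval -0.47 to 1.17) was smaller than the spread between arrays, which ran from 9.39 to 11.73. Its second probe differed by 0.33. The exact permutation within chips gave p = 0.462 and limma an adjusted p of 1.00. The difference was 0.70 within chip 1 and 0.01 within chip 2, and -0.09 without Control 2.

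Slc17a7, encoding VGLUT1 of hippocampal principal neurons, varied far less, at 11.88 ± 0.15 in EtOH and 11.88 ± 0.08 in Control, with a difference of -0.03 (-0.19 to 0.12, exact permutation p = 0.613). Slc17a8, encoding VGLUT3, differed by -0.01 (-0.29 to 0.28, exact permutation p = 0.973).

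**Figure D3:**
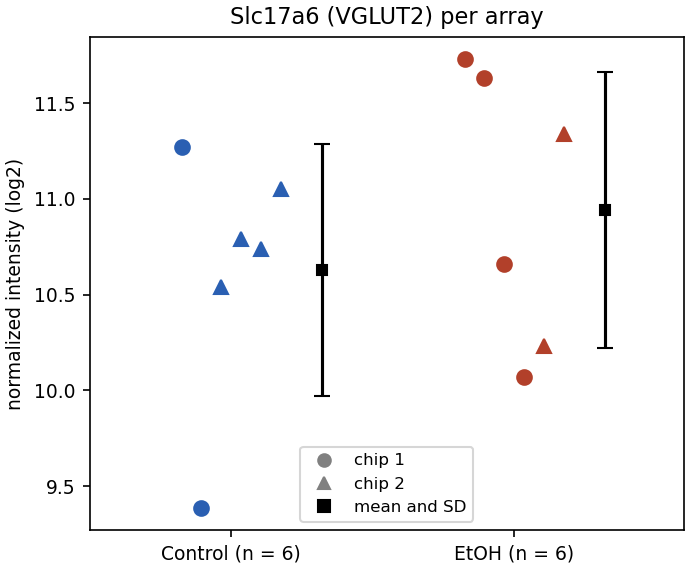
Normalized log2 intensity of Slc17a6 per array, by group (horizontal axis) and chip (symbol), with the group mean and SD (squares and bars, n = 6 each). The groups overlap, and the lowest array, at 9.39, is a Control on chip 1.

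Regulators of DNA methylation had 6 of 14 members higher and a median of -0.01 (camera adjusted p = 0.91). Its mean was 0.02 and its camera direction upward, against the sign of its median. Dnmt3l, a cofactor of the methyltransferases, had the smallest p, with a difference of 0.35 (-0.02 to 0.72). Of 31 histone modifying enzymes 19 were higher, with a median of 0.01 (camera adjusted p = 0.773) and Kdm6b, a demethylase, at -0.12. Of 31 imprinted genes 17 had lower values, with a median of -0.01 (camera adjusted p = 0.492). The imprinted Nnat differed by -0.31 (-0.57 to -0.05).

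Enzymes of ethanol and aldehyde metabolism had a median of -0.03 over 9 genes (camera adjusted p = 0.554), with Adh5 at -0.15. One-carbon and methionine metabolism had a median of -0.01 over 15 genes (0.773), with the thymidylate synthase gene Tyms at -0.18. The oxidative stress response had a median of -0.02 over 20 genes (0.583), with its regulator Nfe2l2 at 0.22. Protein folding and ER stress had a median of -0.04 over 23 genes (0.391), with Atf4 at 0.11 after chip adjustment although its group means were 11.39 in EtOH and 11.41 in Control and its other probe went the opposite way. These values in parentheses are camera adjusted p.

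Cell type lists did not pass either. Granule cells of the dentate gyrus had a median of -0.09 over 11 genes (camera adjusted p = 0.344). In this list Tspan18, a tetraspanin, differed by -0.30 and passed when adjusted over the list alone (adjusted p = 0.0345), but not over all genes in limma (adjusted p = 1.00). Its second probe also had a lower value. CA1 pyramidal cells had a median of 0.06 (camera adjusted p = 0.554), with Wfs1 at 0.22, and CA2 and CA3 cells -0.10 (0.193), with Amigo2 at -0.20. Interneurons had 0.05 (0.583), with Npy (neuropeptide Y) at -0.16, and adult neurogenesis -0.04 (0.595), with the immature neuron gene Dcx at 0.20. Again the parentheses hold camera adjusted p.

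Among glia and vessels the medians were 0.03 for myelin (camera adjusted p = 0.583, Olig1 at 0.08), 0.03 for oligodendrocyte precursors (0.583, Cacng4 at 0.24) and -0.0042 for astrocytes (0.773, Apoe at -0.15). The myelin median was -0.13 within chip 1 and 0.16 within chip 2, each past the camera threshold in its own direction. These calls used the preset correlation of 0.01, whereas the correlation estimated for this list over all arrays was 0.522. With the estimate, camera over all arrays gave an adjusted p of 0.85. Microglia had -0.0088 (camera adjusted p = 0.492, Fcer1g at -0.11). Interferon and inflammation genes had -0.07 (0.193, Oasl2 at -0.41), but -0.16 with a stricter detection filter, where camera called the list (adjusted p = 0.0255). The median was -0.08 for endothelium and pericytes (camera adjusted p = 0.193, Higd1b at 0.23) and -0.08 for ependyma (0.492, Dnah11 at -0.08). Blood genes had 0.06 (camera adjusted p = 0.595, Hbb-bt at 0.07).

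Neighbouring brain regions had medians of 0.10 for neocortex (camera adjusted p = 0.193, Cux2 at 0.50), 0.05 for thalamus (0.554, Ntng1 at 0.29) and 0.06 for striatum (0.595, Rgs9 at 0.12). Glutamate receptors and transporters had 0.02 (camera adjusted p = 0.595, Grm5 at 0.24 with its other probes opposite). GABA receptor subunits had 0.0040 (0.707), with Gabrg1 at 0.29, short of the threshold when adjusted over the list alone (adjusted p = 0.0505). Monoamine and acetylcholine genes had 0.02 (camera adjusted p = 0.91, the muscarinic receptor Chrm1 at -0.20 with its other probe opposite), and neurotrophins and growth factors 0.01 (0.595, Nrg1 at 0.23).

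Housekeeping and rhythm lists had medians near 0. Oxidative phosphorylation had a median of -0.01 over 52 genes (camera adjusted p = 0.583, Cox7b at 0.18) and ribosomal proteins -0.0066 over 38 genes (0.778, Rps3 at -0.13). Circadian clock genes had -0.02 (camera adjusted p = 0.996, Arntl at 0.20), with a mean of -1.16e-05 and an upward camera direction. Glucocorticoid response genes had -0.03 (camera adjusted p = 0.595, Zbtb16 at 0.13). Of the 32 lists that did not pass, 26 changed the sign of their median under at least 1 alternative.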

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

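No tests of this part were chosen after the result was seen. Of 196 sets of 6 arrays examined, 8 held an array far from the others. Chance gives about 9.8 (about 1 in 20) for independent measures that were not selected. Many of these measures were genes picked for a small p on the same arrays, which favours a small spread within groups. Several list means share genes. The 2 counts are therefore not a fair comparison. The ratio given is the array's gap to its nearest neighbour over the range of the group. Control 2 stood out in 3 of them. It had the lowest Ntng1 (9.71, ratio 0.6253), the lowest mean of the interneuron list (9.97, ratio 0.6425) and the highest mean of the endothelium and pericyte list (8.14, ratio 0.715).

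In EtOH, array 3 had the lowest mean of the myelin list (10.22 against 10.56 for the nearest, ratio 0.751). EtOH 4 had the highest Nrg1 (6.26, ratio 0.766) and EtOH 2 the highest Cox7b (7.00, ratio 0.663). EtOH 1 had the lowest Apoe (12.10, ratio 0.637) and EtOH 5 the lowest mean of the striatum list (7.33, ratio 0.6285).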

How the results depend on the processing

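The alternatives around choroid plexus and neocortex, the exact permutation of lists and the reduced meninges list were chosen after seeing the data. Probes past the threshold stayed at 0 in limma under every alternative run, including an adjusted p of 0.1, and the lowest adjusted p was 0.0709, without Control 2. Probes at an unadjusted p under 0.05 numbered 458 with a detection p under 0.01 on all arrays (15259 probes tested) and 1913 with no filter (45281 tested), and between 604 and 919 with 1 array left out. Median scaling in place of quantile normalization gave 378 higher and 193 lower (66.2% higher against 50.4%). The 20 genes with the smallest p kept their sign in all 551 values. They were picked for a small p on these same arrays, which makes a kept sign likely beforehand, so this is no separate support. For the shifts below, the cause was not tested.

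Called lists numbered 0 without the chip term, with an estimated correlation, in fry and in the exact permutation within chips. They numbered 4 with median scaling, 6 within chip 1 and 5 within chip 2. The interferon list was also called with median scaling (-0.025, adjusted p = 0.0183), with the stricter detection filter (-0.16, adjusted p = 0.0255) and without EtOH 4 or Control 1. Choroid plexus was called with median scaling (-0.56) and without EtOH 4 or Control 1, and neocortex with the chip as a random block (0.13) and without EtOH 4 or EtOH 5. With 1 array left out the called lists ran from 1 (without Control 2) to 6 (without EtOH 5), with 5 without EtOH 4 or Control 1 and 4 without EtOH 3. The immediate early median was 0.11 without the chip term, 0.11 within chip 2 (adjusted p = 0.0763) and 0.14 in fry and with an estimated correlation, where the call was lost. It kept its call with any 1 array left out (camera adjusted p 0.000185 to 0.0146). The meningeal median was -0.24 without the chip term and -0.43 within chip 1 (adjusted p = 0.0521), in fry and with an estimated correlation. With 1 array left out it ran from -0.55 to -0.18, and only without Control 2 was the call lost (adjusted p = 0.307). Without Slc13a4, Igf2 and Igfbp2 it was -0.38 and kept its call (adjusted p = 0.00482).

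The labels do not say what a replicate number shares. Correlations of deviations for numbers 1 to 6 were 0.25, 0.27, 0.079, 0.13, 0.19 and 0.16. Number 3 fell short of 0.1, so the numbers were not taken to pair the arrays, although all 6 values were above 0 and a weak pairing is not excluded. The deviations were taken from the group means without the chip. Numbers 3 and 4 had their 2 arrays on different chips and the other numbers on the same chip. Both arrays of numbers 2 and 4 held choroid plexus transcripts. These correlations therefore mix chip and tissue with any pairing and cannot decide it. In the EtOH arrays, only those of numbers 1 and 2 correlated best with the Control array of their own number. The replicate block with the chip term called 0 probes, 917 at an unadjusted p under 0.05, and 9 lists. Beside the immediate early and meningeal lists these were choroid plexus, neocortex, thalamus, granule cells, CA2 and CA3 cells, endothelium and pericytes, and glucocorticoid response. With the replicate block these changed sign: 0.0096 for Slc17a7, -0.019 for the GABA receptor list, 0.072 for clock, 0.076 for glucocorticoid (adjusted p = 0.0118) and 0.016 for astrocyte genes. So did 0.014 for DNA methylation, 0.0074 for imprinted, 0.0063 for one-carbon, 0.021 for oxidative stress, 0.016 for oxidative phosphorylation, 0.0032 for ribosomal and -0.060 for monoamine genes in that block.

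The Slc17a6 difference turned to -0.14 with the neocortex covariate and -0.02 without the 4 choroid plexus arrays, and ran from -0.087 (without Control 2) to 0.65 with 1 array left out. Other sign changes numbered 127 of 895 values over 32 lists and 30 of 1143 over 41 genes. The values with a turned sign passed no test, except the myelin list within chip 1 and the glucocorticoid list with the replicate block. With their sign kept, 31 further values of these lists passed camera under an alternative. Without the chip term the values with a turned sign were -0.022 for Atf4, 0.0045 for Slc17a7, 0.038 for Slc17a8 and 0.023 for Xist. Among lists they were 0.028 for DNA methylation, 0.0063 for imprinted, 0.0050 for one-carbon and 0.015 for protein folding. As a random block the chip gave 0.027 for Slc17a8, 0.0091 for Xist, 0.019 for DNA methylation, 0.0049 for one-carbon, 0.0057 for protein folding and -0.0011 for monoamine genes.

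Within chip 1 the values were -0.052 for Hbb-bt, 0.0047 for Slc17a7, -0.016 for GABA receptors, 0.0086 for clock, -0.13 for myelin (adjusted p = 0.0119), -0.077 for precursor and -0.052 for blood genes. There too, neurogenesis had 0.019, DNA methylation 0.045, oxidative phosphorylation 0.012, ribosomal 0.011, monoamine -0.011 and neurotrophin genes -0.020. Camera called the myelin list in opposite directions on the chips, with 0.16 within chip 2 (adjusted p = 8.69e-07), and the difference between chips was not tested. Camera also called granule cells (-0.24), interneurons (0.15), microglia (-0.10) and protein folding (-0.086) within chip 1, lists whose sign differed within chip 2. Within chip 2 it called oligodendrocyte precursors (0.13), interferon and inflammation (-0.086) and choroid plexus (-0.80). Within chip 2 the turned values were 0.063 for Tyms, 0.11 for Slc17a8, 0.0092 for Xist, 0.033 for granule cell, -0.082 for interneuron, -0.014 for GABA receptor and 0.045 for clock genes. There too, astrocyte genes had 0.056, microglia 0.058, striatum -0.0035, ethanol metabolism 0.020, one-carbon 0.063 and protein folding 0.051.

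Median scaling gave 0.029 for Slc17a8, 0.0034 for Xist, 0.020 for clock, 0.0065 for glucocorticoid, 0.019 for astrocyte and 0.028 for microglia genes. It also gave 0.023 for DNA methylation, 0.013 for imprinted, 0.026 for one-carbon, 0.0061 for oxidative stress and 0.0064 for oxidative phosphorylation. No filter gave -0.0036 for GABA receptor, 0.0044 for DNA methylation and 0.0039 for imprinted genes. The stricter detection filter gave -0.026 for GABA receptor, 0.0078 for clock and 0.0023 for astrocyte genes, and array weights 0.013 for Slc17a8.

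Without the 4 choroid plexus arrays the values were 0.036 for Slc17a8, 0.024 for Xist, -0.0069 for glutamate receptor, -0.086 for GABA receptor, 0.054 for clock and 0.0031 for astrocyte genes. Microglia then had 0.018, DNA methylation 0.0075, ethanol metabolism 0.0055, oxidative stress 0.0097 and ribosomal genes 0.013. Limma gave 0 probes past the threshold there and 731 at an unadjusted p under 0.05, and both list calls held. The choroid plexus covariate gave 0.025 for Slc17a8, 0.020 for clock, 0.0073 for glucocorticoid, 0.0068 for astrocyte, 0.00022 for oxidative stress and, by construction, 0.0086 for choroid plexus genes. The neocortex covariate gave 0.15 for Slc17a8, 0.040 for Xist, 0.019 for granule cell, -0.017 for glutamate receptor, -0.069 for GABA receptor, 0.037 for clock and 0.0092 for glucocorticoid genes. It also gave 0.027 for choroid plexus, 0.085 for ependyma, -0.013 for thalamus, 0.0032 for ethanol metabolism, 0.011 for ribosomal and -0.011 for monoamine genes.

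With 1 array left out, Slc17a7 ran from -0.073 to 0.022, Slc17a8 from -0.11 to 0.089 and Xist from -0.16 to 0.083. Neuronal lists ran from -0.012 to 0.10 (interneuron), -0.013 to 0.046 (glutamate receptor), -0.053 to 0.11 (GABA receptor), -0.011 to 0.040 (monoamine) and -0.088 to 0.018 (neurogenesis). Glial lists ran from -0.035 to 0.093 (myelin), -0.017 to 0.018 (astrocyte) and -0.051 to 0.0086 (microglia). Neighbouring tissue ran from -1.21 to 0.12 (choroid plexus), -0.24 to 0.068 (ependyma), -0.0026 to 0.072 (thalamus), -0.026 to 0.079 (striatum) and -0.052 to 0.12 (blood). The rest ran from -0.082 to 0.069 (clock), -0.10 to 0.012 (glucocorticoid), -0.026 to 0.025 (DNA methylation), -0.034 to 0.038 (imprinted) and -0.046 to 0.013 (ethanol metabolism). One-carbon ran from -0.019 to 0.018, oxidative stress from -0.054 to 0.010, ribosomal from -0.0098 to 0.0078 and neurotrophin genes from -0.017 to 0.031. Dim probes near the detection limit carry the least signal over background.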

Other observations

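For the 3 patterns weighed here the tests were chosen after the result was seen, except the runs with 1 array left out and within each chip, which were fixed beforehand. The tests of Slc6a12 and of the spread between animals, and the regroupings of the arrays, were set before their results were seen.

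Slc17a6 moved with genes of the neocortex over the arrays. Its Pearson correlation with the mean of 13 measured neocortex genes was 0.897 (permutation p = 7e-05, adjusted 0.00028) and Spearman's rho was 0.923 (permutation p = 0.0001, adjusted 0.0004), in a family of 4 relations. It was 0.966 within chip 1 (exact p = 0.00417) and 0.923 within chip 2 (exact p = 0.00139), and 0.885 without the 2 arrays farthest from the median. Of the 13 members 7 had r above 0.5, among them Tbr1 at 0.904, Lamp5 at 0.832 and Cux2 at 0.814, whereas Lmo4 had -0.03, Stard8 -0.32 and Nectin3 -0.49. These genes were chosen after their values were seen. All 13 were detected on all 12 arrays, with mean levels of 13.77 for Lmo4, 11.70 for Fezf2 and 11.39 for Mef2c, so their presence alone does not tell cortex from hippocampus.

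A candidate explanation is that the dissections took along differing amounts of adjoining cortex. The correlation of 0.897 is what this needs, although the members did not all go with Slc17a6, and with the neocortex list mean as a covariate the Slc17a6 difference became -0.14. Thalamus, where Slc17a6 is abundant, stays open: Tcf7l2 and Prkcd gave r = -0.319 (permutation p = 0.313, adjusted 0.418; rho -0.06, permutation p = 0.852), but the list without Slc17a6 gave 0.514 (permutation p = 0.0907, adjusted 0.181) and rho 0.608 (permutation p = 0.0401, adjusted 0.0802), with r 0.494 within chip 1 (exact p = 0.279), 0.622 within chip 2 (exact p = 0.186) and 0.538 without the 2 farthest arrays. Choroid plexus could not be tested over all arrays, which form separate clusters, and within the 8 arrays below the gap r was 0.152 (exact p = 0.714, rho 0.238, exact p = 0.582). A biological difference in cortical-type neurons within the hippocampus was not tested.

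For the higher values of immediate early genes, a uniform shift between chips was already removed by the chip term in the fit. The medians within the chips, 0.21 and 0.11, had the same sign but were no further test of that cause. The within-chip permutation (exact p = 0.04) bears on chance and not on the chip. Chance stays open, since that p was 0.879 after adjustment over 34 lists. No single array carried the pattern, since the median stayed at 0.12 or above with any 1 left out. Neighbouring neocortex stays open. With its mean without shared genes as a covariate, the list mean went from 0.16 (95% interval 0.02 to 0.29) to 0.133 (-0.01 to 0.28), an interval that includes 0. With a neocortex mean that included the shared Nr4a2, camera at its preset correlation kept its call (median 0.14, adjusted p = 0.0115). Handling before death, which moves these genes within minutes, was not tested, and the exposure itself stays among the open explanations.

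The lower values of meningeal genes belong to a list picked for its call, for which chance stays open. Choroid plexus carried over is argued against as the whole cause only so far as the plexus mean measures it. For this test Slc13a4, Igf2 and Igfbp2 were left out. The mean of the other 10 members went from -0.28 (-0.63 to 0.06) to -0.209 (-0.40 to -0.02) with the plexus mean as a covariate. The median of the whole list went from -0.43 to -0.26. These 10 members were not independent of the plexus arrays: Mgp stood at 10.32 to 10.99 on those 4 arrays and at 9.50 to 10.47 on the others. One array mattered, since the median of the whole list was -0.18 without Control 2. With all 4 plexus arrays left out, Control 2 among them, that median was -0.30. Camera at its preset correlation then kept its call (adjusted p = 0.000152). Members varied together within groups (inter-gene correlation 0.428 over all 13 members, Slc13a4, Igf2 and Igfbp2 included). Differing amounts of meninges on the dissected tissue would give this, but so would carried-over plexus, so the correlation cannot tell them apart. Dcn, which the CA1 list also holds, differed by -0.24 (-0.84 to 0.35), at 11.60 in EtOH and 11.73 in Control. A biological change in these cells stays open and untested.

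Other divisions of the arrays give a rough guide to how far chance goes. Among 100 of the 462 divisions into 6 and 6, the real one included and each fitted with the chip term, all 100 gave at least the real count of 0 probes past the threshold, which a count of 0 fixes beforehand, with 8 as the highest other. At an unadjusted p under 0.05, 83 of 100 gave at least 702 probes. The other divisions had a median of 951 and a highest count of 2600, and what made that count high was not tested. At least 2 called lists came from 81 of 100, the highest other being 11. The divisions kept neither the number of each group per chip nor the even share of plexus arrays between the groups. Their counts are therefore not like for like with the real one. Chance cannot be excluded for the called lists, since neither passed the exact permutation within chips after adjustment.

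Slc6a12, the named gene with the smallest p, was hypothesised to follow the amount of meninges. Its difference of -0.70 became -0.579 (95% interval -0.87 to -0.29) with the meninges list mean as a covariate. That mean included Slc13a4, Igf2 and Igfbp2. It ran from 8.656 to 9.016 on the 4 arrays with choroid plexus transcripts and from 7.642 to 8.138 on the others, so it also follows the plexus. The covariate therefore cannot decide how much of the difference the amount of meninges made up. Chance stays open, since the gene was picked for its small p and passed no threshold over all probes (adjusted p = 1.00). A further hypothesis was that exposure widened the spread between animals. The median log2 ratio of residual variance, EtOH over Control, was 0.14 over 20172 probes, and 128 of the arrangements within chips gave one as large in size (exact p = 0.569, highest other 0.44), so no such widening was found.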
